A study of Mus musculus with 14 samples.

How the data were processed

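Gene expression was measured on Illumina BeadChip arrays in mouse intestinal organoids, small epithelial structures grown from intestinal crypts in matrix. Per the labels, tamoxifen was given for 2 days to switch on a Cre recombinase driven by the villin promoter, which is active in the intestinal epithelium. Cultures carried floxed Apc alone or floxed Apc together with floxed Prox1. Organoids that had lost Apc were then selected by culture without the Wnt agonist R-Spondin1 for 5 days, and RNA was compared 7 days after tamoxifen. The labels name 2 genotypes, 2 series and 14 entries, with the same strain and age for all. Total RNA was extracted with a column kit that includes DNase treatment and turned into biotinylated cRNA, per the labels' protocols.

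The values used are those of the authors' deposited table of 45281 probes. Each deposited value is a ratio, and the values themselves show of what: within each series every probe has a median of 1.0, and each probe's ratios in a series become whole steps of 0.01 when multiplied by 1 number. The deposited ratio was therefore read as a log2 expression value divided by the probe's median log2 value over its series. The divisors were searched between 6.0 and 16.0, and log2 values were recovered for 45255 probes, with 26 left out because their divisors were not settled. Only 6702 probes had 1 possible divisor in both series. For the others the smallest divisor of each series was taken, and a probe was kept where these were also the closest pair between the series. A divisor that is a multiple of the one taken would place such a probe at a higher level with larger differences. The recovered values run from 6.35 to 15.23, and the log base was taken from that range, since no header or label states it. Among 4000 simulated probes, built with the same form of ratio, those with settled divisors were recovered exactly in 100.0% of cases. How the authors corrected background and normalized is not given in the sources used here. Within each series the arrays differed by at most 0.02 log2 at 99.98% of ranks, which is the trace of a quantile normalization. The median of each array lay close to the floor of about 6.7, so fold changes of dim genes are understated. The deposited non-normalized table was left out, because its 28 columns of values, 14 of them signals, carry names that match no label. The planned analysis would have started from that table, with background correction and detection p-values. Neither was available from the ratio values, so the tests ran on the recovered log2 values, and the number of arrays limits the precision.

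Before any averaging, all 91 pairs of entries were compared probe by probe. Entries were taken as copies of 1 array when no probe differed by more than 0.02 log2 after the quantile normalization over all 14 entries described below. That step gives equal ranks equal values. As recovered, the series lay on different scales, with upper quartiles of 7.38 and 7.01, so the comparison is one of ranks. The limit was met by 2 pairs, so the 14 entries hold 12 different arrays. Apc-Prox1-deleted series 1 replicate 4 and Apc-deleted series 2 replicate 2 differed by at most 0.0111 log2, although their labels give different genotypes. Apc-Prox1-deleted series 1 replicate 3 and Apc-Prox1-deleted series 2 replicate 2 differed by at most 0.0132 log2. The largest probe difference in every other pair was at least 1.1671 log2. The labels do not settle the group of either array, and a group was not taken from the values, so the 4 entries entered no comparison. The comparisons rest on 10 libraries: 4 Apc-deleted and 2 Apc-Prox1-deleted in series 1, and 2 of each genotype in series 2. The design fixed before the data were examined used all 14 entries. The set of 10 was chosen after results had been seen, in steps. All 14 entries gave 2535 called probes over both series. A set of 11 libraries, with the array of both series placed in series 2 from its position on the main axis of variation, gave 3727. The set of 10 gave 3362 and was kept because the other placement had relied on the values. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

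Values were quantile normalized over all 14 entries with limma 3.58.1 in R 4.3.3, and the 10 libraries were then taken from them. A probe was kept when it exceeded the 50th percentile of the array, about 6.78 log2, on at least 3 of these 10 libraries, which left 26347 probes and removed 18908. A probe above that level in only 2 libraries is removed by this filter. Where the planned filter used detection p-values, this one replaced it. Linear models were fitted with lmFit and eBayes with a variance trend. The comparison over both series had terms for series and genotype, with 7 residual degrees of freedom. The comparisons within each series and the test of their difference came from a fit of the 4 groups, with 6. Benjamini-Hochberg adjusted p under 0.05 was taken as passing, and differences are Apc-Prox1-deleted minus Apc-deleted on the log2 scale. Genes were named from the platform annotation given with the files. Of the recovered probes 34865 had 1 gene symbol, 18 had several and 10372 had none, and no name was taken from a probe with several. Together they named 19052 genes, and 34787 probes were found by gene number in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for the order of genes. Where a gene had several kept probes, the one with the highest mean stood for it, which gave 13474 genes.

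Most genes named in the text follow a rule fixed before the data were examined. Prox1, Apc, Lgr5, Anxa1 and Flna are always named. The others are the 12 largest rises and 12 largest falls with the same sign in both series, the 5 largest of each direction in the other contrasts, and up to 4 members of each list with the smallest adjusted p. Provisional symbols were skipped, and where no member of a list passed, the 2 brightest are given as values. Outside this rule, Myl9, Ccnd1, Olfm4, Col1a2, Dcn, Fn1, Reg3a, Defa31, AY761185, the Y-linked genes Eif2s3y, Kdm5d and Uty, and Neurog3, Sct, Gcg, Phlda3, Zmat3, Gtse1, Cbr3, Gclm, Apcdd1, Dkk3, Sp5 and Axin2 were named after their values were seen. A further 24 gene lists were fixed in the same way: intestinal stem cell, Wnt/beta-catenin targets, fetal-like and regenerative epithelium, YAP/TEAD targets, actin cytoskeleton and annexins, Paneth cell, goblet cell, enteroendocrine cell, tuft cell, absorptive enterocyte, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, Notch pathway, BMP and TGF-beta targets, p53 targets and apoptosis, unfolded protein and integrated stress response, cholesterol biosynthesis, interferon response and MHC, NF-kB and inflammation, glutathione and NRF2 targets, and markers of fibroblasts, immune cells and endothelial or lymphatic cells. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance.

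The fits were tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold among 26347. Of those changed 2-fold, 99% were recovered over both series, 94% in series 1, 97% in series 2 and 78% in the test of the difference between series. For the series contrast itself the share was 97%. The simulated changes were added in full to probes of any level, with no floor. On the arrays the floor compresses changes of dim genes, so these shares may overstate the recovery of such genes. A simulated raised list was called, and 0 of the other lists were. The simulated noise was independent between genes, so it cannot show how often correlated genes give false list calls. Alternatives covered the normalization between arrays, the filter, the series term, a replicate block, array weights, the variance prior, a 1.5-fold threshold, single series and leaving out each library. After the data had been seen, other ways of counting the arrays with conflicting labels, the ratios as deposited, and a run without X and Y genes were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.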

Results

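The study compared mouse intestinal organoids that had lost Apc, the brake on Wnt signalling, with organoids that had lost both Apc and the transcription factor Prox1. The question was which genes Prox1 controls in Apc-mutant intestinal epithelium. RNA was profiled 7 days after tamoxifen on whole-genome bead arrays, in 2 series. After 2 arrays that had been deposited under conflicting labels were set aside, series 1 held 4 Apc-deleted and 2 Apc-Prox1-deleted libraries, and series 2 held 2 of each. Levels are on a log2 scale with a floor of about 6.7. The first principal component of the 10 libraries held 52.9% of the variance and separated the series, and the second held 24.6% and separated the genotypes within each series. Every library correlated best with another of its own group, at r of 0.99 or above across probes.

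Prox1, the gene deleted between the genotypes, was lower in the Apc-Prox1-deleted organoids of both series. Its brighter probe averaged 9.81 ± 0.47 (SD, n = 4) in Apc-deleted and 8.07 ± 0.31 (n = 2) in Apc-Prox1-deleted organoids of series 1. In series 2 the means were 10.48 ± 0.61 (n = 2) and 9.09 ± 0.62 (n = 2). Over both series it was 3.02-fold lower, a log2 difference of -1.60 (SE 0.22, limma adjusted p = 0.000186), and within each series every Apc-Prox1-deleted library lay below every Apc-deleted one. The difference was -1.75 in series 1 (adjusted p = 0.000948) and -1.39 in series 2 (adjusted p = 0.0259). A dimmer probe gave -1.48 (SE 0.19, adjusted p = 8.31e-05) and lay near the floor after deletion. Across series the brighter probe overlapped: Apc-Prox1-deleted series 2 replicate 3, at 9.53, lay above the lowest Apc-deleted library of series 1, at 9.42. With all 14 entries as labelled, the Prox1 difference was -1.08. The labels do not say which exons were removed, so neither probe is known to lie in the deleted part. Apc, deleted in both genotypes, did not pass (0.13, SE 0.07, adjusted p = 0.239). Its probe lay near the floor, with group means from 7.12 to 7.53, so a difference would be understated.

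**Figure D1:**
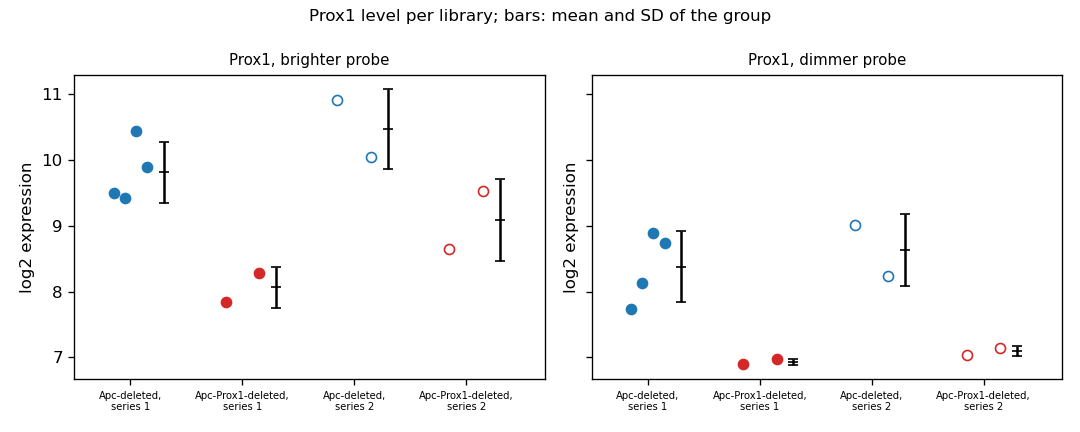
Log2 level of Prox1 for its brighter probe (left) and dimmer probe (right) in each library of the 4 groups, with points for libraries and bars for the mean and SD of the group. Within each series both probes were lower in each Apc-Prox1-deleted library than in any Apc-deleted one.

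Over both series, Vim, which encodes the intermediate filament protein vimentin, had the largest fitted fall among the probes tested after deletion of Prox1. Vim was 12.1-fold lower (-3.60, SE 0.39, adjusted p = 2.16e-05), and its mean went from 10.24 to 6.98 in series 1 and from 11.46 to 7.41 in series 2, where the floor understates the fold. The secreted Wnt inhibitor Notum was 8.85-fold lower (-3.15, SE 0.25), and the Wnt feedback inhibitor Nkd1 was 5.03-fold lower (-2.33, SE 0.21). Sbspon (5.60-fold), the zinc transporter Slc30a2 (5.09-fold), Bex4 (4.73-fold), the cell cycle inhibitor Cdkn1c (3.91-fold) and the sodium channel subunit Scn2b (3.91-fold) also fell. So did Pla2g2a (3.37-fold), the kinase Dmpk (3.33-fold), the gut hormone ghrelin, Ghrl (3.32-fold), and the actin-bundling protein Espn (3.29-fold). The stem cell receptor Lgr5 was 1.92-fold lower (-0.94, SE 0.15, adjusted p = 0.000523).

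Among genes with a symbol, each read through its brightest probe, the largest rise was in Capg, an actin filament capping protein, at 4.87-fold (2.28, SE 0.20, adjusted p = 3.09e-06). It was followed by Crip2 (4.50-fold), the keratinocyte envelope protein loricrin, Lor (4.24-fold), and Wfdc2 (4.07-fold). The small GTPase Rab15 rose 3.72-fold, the aldo-keto reductase Akr1b8 3.66-fold, Psca 3.65-fold and Tomm22, of the mitochondrial import pore, 3.48-fold. The tight junction protein F11r (3.27-fold), mesothelin, Msln (3.21-fold), Mpp1 (3.17-fold) and Uap1 (3.13-fold) completed the 12 largest rises with the same sign in both series. A probe without a gene symbol rose more than any of them (3.04 over both series, adjusted p = 0.00312). Anxa1, encoding annexin A1, rose 1.46-fold (0.55, SE 0.09, adjusted p = 0.000455), while filamin A, Flna, did not pass (0.16, SE 0.11, adjusted p = 0.431). The rises of Psca, Tomm22, Msln and Anxa1 differed between series. Psca and Tomm22 did not pass over both series with a robust variance prior (adjusted p = 0.0532 and 0.0518) or with the deposited ratios tested as they are (0.822 and 0.958). In the ratio run the variance trend followed each probe's mean ratio, not its expression level, so a loss there may come from that trend.

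In all, 3362 of 26347 probes passed over both series, 1567 higher and 1795 lower, standing for 2390 genes, and 922 of them changed at least 1.5-fold. With all 14 entries as the design had planned, 2535 passed. Leaving out Apc-Prox1-deleted series 1 replicate 2 gave 1921, leaving out replicate 1 of that group gave 2087, the series 2 libraries alone gave 725, and entering the array with both genotype labels as Apc-Prox1-deleted series 1 gave 1666. Without the series term 918 passed, and with array weights 5098. The 14 entries hold 1 array under both genotypes and another under both series. Losses in that run, here and below, therefore cannot tell a weak effect from the conflicting labels. The calls of Psca, Anxa1 and Pla2g2a were lost with all 14 entries (adjusted p = 0.162, 0.0755 and 0.111), and those of Lgr5, Anxa1, Psca and Tomm22 with the series 2 libraries alone (0.128, 0.144, 0.369 and 0.499). With the deposited ratios tested as they are, those of Id3, Chac1, Trib3, Ccn2 and Ddit3 were lost (0.805, 0.68, 0.542, 0.165 and 0.143). The variance trend on mean ratios may have caused these losses too, so they do not decide the calls.

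Among the 24 gene lists, 5 were higher after Prox1 deletion at the preset correlation. None of the 12 list calls, 5 higher and 7 lower, held with an estimated correlation, where the smallest adjusted p was 0.112. Of 25 measured members of the actin cytoskeleton and annexin list, 13 rose, 1 fell and 11 did not pass (camera adjusted p = 5.37e-07, adjusted p = 0.112 with an estimated correlation). Besides Capg these included Anxa8 (0.74, SE 0.08), Anxa3 (1.10, SE 0.14) and gelsolin, Gsn (0.61, SE 0.08), and the member that fell was the myosin light chain Myl9 (-1.21, SE 0.32), whose call was lost without Apc-Prox1-deleted series 1 replicate 2 (adjusted p = 0.0737), Apc-Prox1-deleted series 2 replicate 1 (0.0719) or Apc-deleted series 2 replicate 3 (0.0534) and with a robust variance prior (0.149). Of 15 genes of fetal-like and regenerative epithelium, 8 rose, 0 fell and 7 did not pass (adjusted p = 2.67e-06, adjusted p = 0.112 with an estimated correlation). They included Msln, Krt19 (0.73, SE 0.09), Anxa3 and the gap junction gene Gja1 (0.82, SE 0.11). Of 22 glutathione and NRF2 targets, 11 rose and 0 fell (adjusted p = 1.53e-05, adjusted p = 0.296 with an estimated correlation), led by Gpx2 (1.33, SE 0.11), Gsta4 (1.38, SE 0.15), Srxn1 (0.69, SE 0.11) and Ephx1 (0.98, SE 0.15).

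Of 20 p53 targets and apoptosis genes, 12 rose, 1 fell and 7 did not pass (camera adjusted p = 4.27e-05, adjusted p = 0.127 with an estimated correlation). Mdm2, the p53 ubiquitin ligase, was 2.97-fold higher (1.57, SE 0.15), and Ccng1 (1.32, SE 0.15) and the death receptor Fas (0.88, SE 0.08) rose, while Gadd45a fell (-1.12, SE 0.11). The YAP/TEAD targets were higher as a list on 3 of 15 members, Ccn2 (2.84-fold, log2 SE 0.28), Axl (0.63, SE 0.13) and Ptpn14 (0.43, SE 0.10), with 0 falling and 12 not passing. That list had an adjusted p = 0.0198, an adjusted p = 0.282 with an estimated correlation, and an adjusted p = 0.0903 with the series 2 libraries alone. Adjusted over the list alone, the members that rose numbered 13 in the actin list, 11 in the fetal-like list, 13 in the glutathione list, 15 in the p53 list and 3 in the YAP/TEAD list. On the same adjustment 1 actin, 2 glutathione and 2 p53 genes fell.

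A further 7 lists were lower. The enteroendocrine list, markers of the hormone-secreting cells of the gut, had the smallest p of the 24: 15 of 27 members fell, 0 rose and 12 did not pass (camera adjusted p = 2.05e-09, adjusted p = 0.112 with an estimated correlation). Ghrl, secretogranin 2, Scg2 (-0.77, SE 0.09), the islet transcription factor Isl1 (-0.58, SE 0.08) and Cryba2 (-0.71, SE 0.11) had the smallest p-values. The median of the enteroendocrine list was -0.66 in series 1 but only -0.17 in series 2. At the preset correlation its call was kept with the series 2 libraries alone. Of 21 Wnt/beta-catenin targets, 12 fell, 2 rose and 7 did not pass (adjusted p = 8.24e-05, adjusted p = 0.26 with an estimated correlation). Sox4 (-1.05, SE 0.11) fell with Notum and Nkd1, while Cd44 (0.95, SE 0.15) and the cyclin Ccnd1 (0.74, SE 0.15) rose. Of 23 stem cell genes, 10 fell and 0 rose (adjusted p = 0.00133, adjusted p = 0.201 with an estimated correlation). Scn2b, Tnfrsf19 (-1.06, SE 0.13), Rgmb (-0.94, SE 0.12) and Aqp4 (-1.07, SE 0.16) led them, and Olfm4 was at 0.14 (SE 0.23).

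Of 25 hypoxia and glycolysis genes, 7 fell and 0 rose (camera adjusted p = 8.47e-05, adjusted p = 0.26 with an estimated correlation), among them Vegfa (-0.82, SE 0.12), Car9 (-0.89, SE 0.15), Pdk1 (-0.69, SE 0.13) and Ndrg1 (-1.12, SE 0.23). Of 15 BMP and TGF-beta targets, 6 fell and 2 rose (adjusted p = 0.00664, adjusted p = 0.112 with an estimated correlation). Id3 (-1.16, SE 0.12), Tgfbi (-1.70, SE 0.22), Id1 (-1.03, SE 0.14) and Id2 (-0.91, SE 0.16) fell. This list did not pass with all 14 entries (adjusted p = 0.245), nor did Id3 (0.0567) or Id2 (0.293). Of 13 Paneth cell genes, which encode products of the antimicrobial cells of the crypt base, 3 fell, Defa26 (-1.21, SE 0.11), Pla2g2a and Defa21 (-0.72, SE 0.15), and 0 rose. Another member, Defa31, named after its values were seen, was removed by the filter and went the other way: its 2 probes averaged 14.59 ± 0.04 and 14.55 ± 0.22 (n = 2) in Apc-Prox1-deleted series 2 organoids and stayed at or below 6.79 in the libraries of the other groups. With no filter on dim probes the list had an adjusted p = 0.024. The Paneth call (adjusted p = 0.018, adjusted p = 0.298 with an estimated correlation) was lost without Apc-Prox1-deleted series 1 replicate 2 (adjusted p = 0.066), with cyclic loess (0.0543) and with the series 2 libraries alone (0.133). The goblet cell list passed on 1 of 17 members, the transcription factor Foxa3 (-0.74, SE 0.11), with an adjusted p = 0.0419 and an adjusted p = 0.507 with an estimated correlation. Its call was lost when any 1 of the 6 series 1 libraries was left out (adjusted p = 0.0535 to 0.259), with no filter (0.0517), with the filter met on all arrays (0.113) and by fry (0.105). Adjusted over the list alone, 22 enteroendocrine, 14 Wnt, 10 stem cell, 10 hypoxia, 9 BMP, 6 Paneth and 4 goblet genes fell, while 2 Wnt and 2 BMP genes rose.

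**Figure D2:**
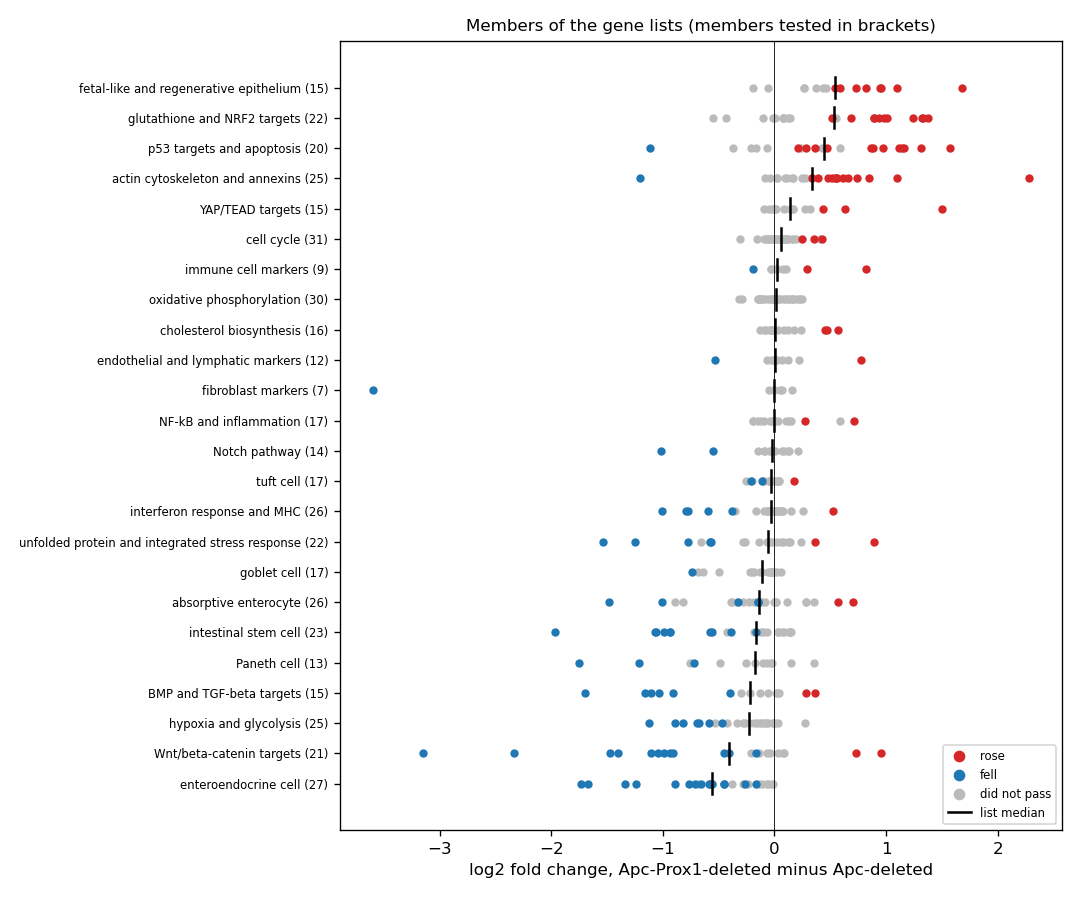
Log2 fold change over both series (horizontal axis) of each measured member of the 24 gene lists (vertical axis), with members that rose in red, that fell in blue and that did not pass in grey, and the list median as a black bar. The medians run from -0.56 in the enteroendocrine list to 0.55 in the fetal-like list.

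The remaining 12 lists did not pass at the preset correlation, with adjusted p from 0.114 to 0.668. The absorptive enterocyte list (0.114) was called lower with only series 1 libraries (adjusted p = 0.000113), with array weights (0.00755), without Apc-deleted series 2 replicate 1 (0.0195) and without Apc-Prox1-deleted series 2 replicate 3 (0.00231). The tuft cell list was called with only series 1 libraries (adjusted p = 0.0459) and by fry (0.00852), and the cell cycle list without Apc-deleted series 2 replicate 3 (0.0438). In the absorptive enterocyte list 2 of 26 members rose and 5 fell: sucrase-isomaltase, Sis (-1.48, SE 0.33), and Ace (-0.33, SE 0.06) fell, and Apob (0.57, SE 0.11) and Cyp3a13 (0.71, SE 0.20) rose. Of 22 unfolded protein and integrated stress response genes, 5 fell, including Trib3 (-1.25, SE 0.26), Chac1 (-1.54, SE 0.34), Xbp1 (-0.57, SE 0.13) and Ddit3 (-0.77, SE 0.18), and 2 rose. Of 26 interferon and MHC genes 5 fell, Ifitm3 (-0.79, SE 0.12), H2-T23 (-0.77, SE 0.14) and Ifi27 (-1.01, SE 0.25) among them, and 1 rose, H2-D1 (0.53, SE 0.13). In the Notch list, Hes6 (-1.02, SE 0.18) and Hes1 (-0.55, SE 0.17) fell among 14 members. Of 31 cell cycle genes 3 rose, Cdc20 (0.43, SE 0.11), Rrm2 (0.36, SE 0.10) and Ect2 (0.24, SE 0.08), and of 16 cholesterol genes 3 rose, Mvk (0.46, SE 0.10), Cyp51 (0.47, SE 0.12) and Lss (0.57, SE 0.17). Icam1 (0.71, SE 0.08) and Il18 (0.27, SE 0.07) rose among 17 NF-kB genes, a list whose median was -0.007, mean 0.07 and test direction up. In the tuft cell list Vav1 (-0.21, SE 0.05) and Kctd12 (-0.11, SE 0.03) fell and Alox5 (0.18, SE 0.05) rose among 17. No member of 30 oxidative phosphorylation genes passed in limma, and the brightest, Atp5b (0.09, SE 0.05) and Cox5b (0.01, SE 0.07), are given as values. Of these genes, the calls of Cyp3a13, Xbp1, Ddit3, Ifi27, H2-D1, Hes1, Cdc20, Rrm2, Ect2, Mvk, Cyp51, Lss, Il18, Vav1, Kctd12 and Alox5 were each lost on leaving out at least 1 library (adjusted p = 0.0503 to 0.174). Those of Sis, Trib3, Chac1 and Ifi27 were lost with a robust variance prior (adjusted p = 0.0843, 0.0573, 0.0845 and 0.0817). Adjusted over the list alone, 4 enterocyte genes rose and 8 fell, 2 stress response genes rose and 7 fell, 1 tuft cell gene rose and 3 fell, and 2 cell cycle genes rose.

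The lists of markers of cells other than epithelium were not called by camera (adjusted p = 0.668 for fibroblast, 0.297 for immune and 0.637 for endothelial and lymphatic markers). By fry, which does not compare a list with other genes, the fibroblast (adjusted p = 0.00852) and immune cell markers (0.0357) passed, and the endothelial and lymphatic markers (0.404) did not. Of 7 measured fibroblast markers only Vim fell, and the rest did not pass: Col1a2 was at 0.05 (SE 0.04), Dcn at -0.01 (SE 0.04) and Fn1 at 0.07 (SE 0.04), with group means of these 3 genes between 6.73 and 6.88. The list's median was -0.002 and its mean -0.483. Of 9 immune markers Cd14 (0.82, SE 0.11) and Laptm5 (0.30, SE 0.06) rose and Cd79b (-0.19, SE 0.05) fell. Of 12 endothelial and lymphatic markers, Pdpn (0.78, SE 0.16) rose and Egfl7 (-0.54, SE 0.13) fell. The Egfl7 call was lost without Apc-Prox1-deleted series 1 replicate 2 (adjusted p = 0.0935), and the Pdpn call with a robust variance prior (0.0621).

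Within series 1, the comparison of 4 Apc-deleted with 2 Apc-Prox1-deleted libraries, Psca (3.01, adjusted p = 8.33e-10), Tomm22 (2.92), Crip2 (2.73), Wfdc2 (2.63) and Capg (2.55) had the largest fitted rises among genes with a symbol, each read through its brightest probe. Psca and Tomm22 were near the floor before deletion (7.24 and 7.01). A dimmer probe of Mgmt rose by 2.72. The probe without a symbol rose by 5.14 here (adjusted p = 7.99e-12). The named falls were those of Notum (-3.28, adjusted p = 6.75e-06), Vim (-3.26), Xist (-3.16), the islet-regenerating gene Reg1 (-2.74) and Bex4 (-2.68). Vim and Xist lay next to the floor after deletion, at 6.98 and 6.68, so their falls are understated and no order is given. Xist, the noncoding RNA of the inactive X chromosome, averaged 9.84 ± 0.39 (n = 4) in Apc-deleted series 1 organoids and between 6.65 and 6.68 in the other groups. A probe of the Y-linked gene Eif2s3y averaged 8.27 ± 0.06 (n = 2) in Apc-Prox1-deleted series 1 organoids, against 6.72 ± 0.10 in the Apc-deleted organoids of that series. The remaining 7 Y-linked probes, of Eif2s3y, Kdm5d and Uty, averaged between 6.61 and 7.00 in the former and between 6.63 and 6.92 in the latter. Of these, a Kdm5d probe stood at 6.99 ± 0.07 against 6.69 ± 0.06, and the rest differed less, in either direction. In series 2 the first Eif2s3y probe averaged 7.03 ± 0.07 in Apc-deleted and 6.72 ± 0.01 in Apc-Prox1-deleted organoids. Xist was at the floor there too, so these probes do not settle sex in series 2. Xist and the first Eif2s3y probe separated the genotypes of series 1. A sex difference between animals cannot be told apart from Prox1 deletion in series 1, and the calls over both series include these libraries. In series 1, 2192 probes passed, 1052 higher and 1140 lower. The count was 772 without Apc-Prox1-deleted replicate 1 and 740 without replicate 2, 4611 with array weights, and 1001 with the array of both genotypes counted in this group. The Vim call in series 1 was lost with a robust variance prior (adjusted p = 0.0556), and those of Psca and Bex4 with all 14 entries (0.0783 and 0.0649).

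Within series 2, with 2 libraries of each genotype, Rab15 (2.22, adjusted p = 4.67e-05), Capg (1.93), Gsta1 (1.86), Plekhs1 (1.76) and Mpp1 (1.73) had the largest rises among genes the naming rule covers. The defensin-related AY761185, which has a provisional symbol, rose more (4.03, adjusted p = 2.62e-13), as did 2 probes without a symbol (3.89 and 2.44) and, removed by the filter, Defa31. Vim (-4.05, adjusted p = 0.000433), Sbspon (-3.16), Notum (-2.96), Sema7a (-2.63) and Scn2b (-2.55) had the largest fitted falls among genes the naming rule covers. Sema7a and Scn2b lay next to the floor after deletion (6.68 and 6.84). A probe without a symbol, at -2.57, fell more than Scn2b. Here 1086 probes passed, 451 higher and 635 lower. The count was 467 without Apc-deleted replicate 1, 413 without Apc-Prox1-deleted replicate 1, between 377 and 394 under other normalizations, and 186 with all 14 entries. With the array of both series it was 1632 when counted in series 2 and 352 in series 1. The Vim call in series 2 was lost with a robust variance prior (adjusted p = 0.066), and those of Notum and Gsta1 with all 14 entries (both 0.0603). Of the 1086 probes, 978 (90.06%) moved the same way in series 1. Both series called 239 probes higher and 348 lower, where independent lists would share 18.01 and 27.48, and 19 were called in opposite directions. Both comparisons came from 1 fit and share each probe's variance estimate, so the excess over independent lists may be overstated. The log2 fold changes of the series, which share no libraries, correlated across all probes with r = 0.65 (rho = 0.522), and probes are not independent replicates.

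**Figure D3:**
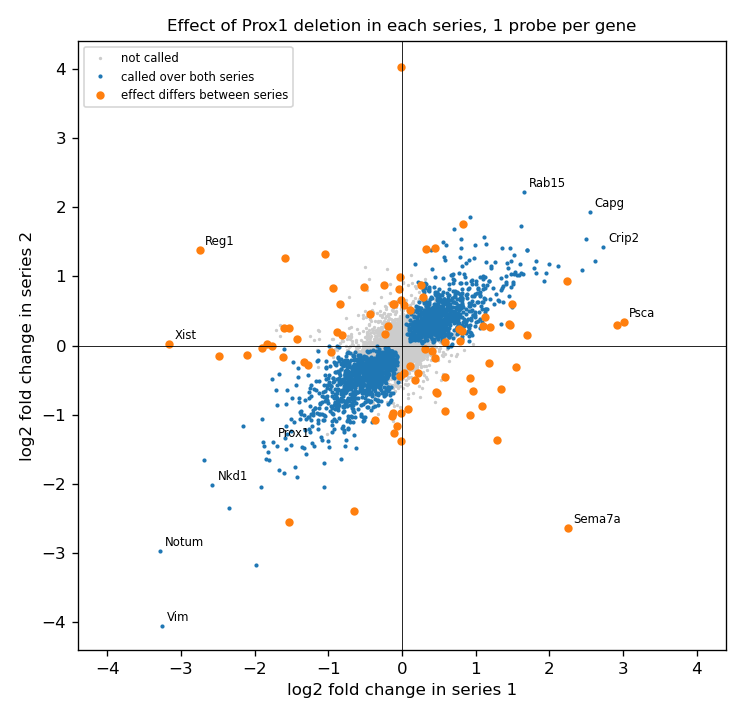
Log2 fold change of each of 13474 genes in series 1 (horizontal) against series 2 (vertical), with 2134 genes called over both series in blue and 83 whose effect differed between series in orange. Vim, Notum and Nkd1 lie low in both series, whereas Sema7a lies at 2.26 in series 1 and -2.63 in series 2.

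The effect of Prox1 deletion differed between series for 148 probes, 70 with a higher effect in series 2 and 78 with a lower one. Sema7a, a semaphorin, rose by 2.26 in series 1 and fell by 2.63 in series 2 (difference -4.89, adjusted p = 1.69e-11). Reg1 (difference 4.12), Prelp (2.86) and Cptp (2.37) fell in series 1 and rose in series 2. Xpnpep2 (-2.66) and Cyp11a1 (-1.97) rose in series 1 and fell in series 2. For Psca (-2.68) and Tomm22 (-2.62) the series 1 rise was not matched in series 2, where their differences were 0.34 and 0.30. Xist (3.18) and Sis (2.33) fell in series 1 and stood at 0.02 and -0.15 in series 2. Anxa1 also differed, with 0.78 in series 1 and 0.24 in series 2 (adjusted p = 0.0442). Among genes with a place on a chromosome, 15 of the 82 were called in both series with opposite signs. The count of probes was 66 and 75 without Apc-Prox1-deleted series 1 replicate 1 or 2, 69 without Apc-deleted series 2 replicate 1, 53 with all 14 entries, 64 with the filter met on all arrays, 73 with no variance trend and 234 with both arrays of conflicting labels under their series 2 labels. The calls of Psca and Xpnpep2 were lost with all 14 entries (adjusted p = 0.666 and 0.535), and that of Sis with no variance trend (0.0505).

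**Figure D4:**
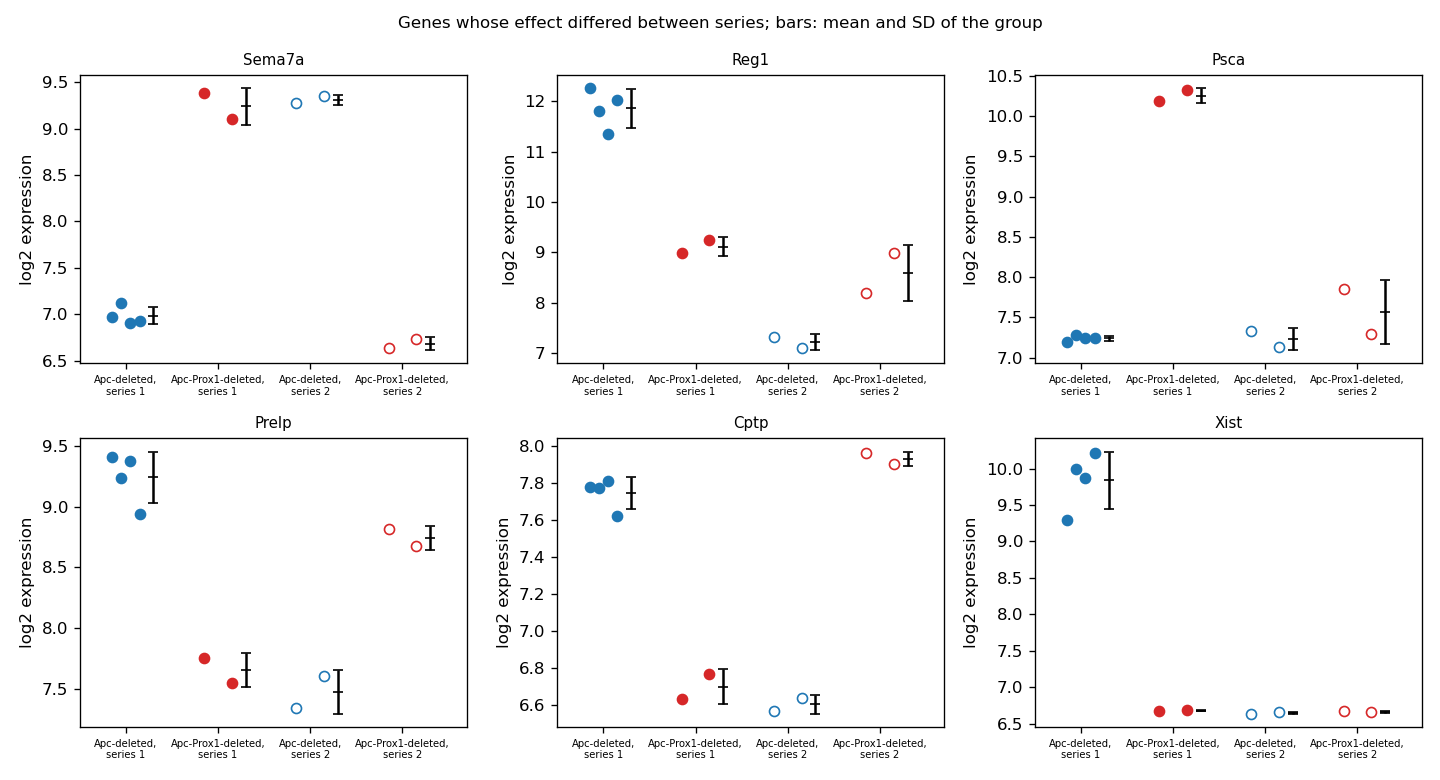
Log2 level per library of Sema7a, Reg1, Psca, Prelp, Cptp and Xist in the 4 groups, with points for libraries and bars for the mean and SD of the group. Sema7a averaged 9.24 in Apc-Prox1-deleted series 1 and 9.31 in Apc-deleted series 2 organoids, against 6.98 and 6.68 in the other groups.

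Between the series, with genotype in the fit, 12506 probes differed, 6535 higher in series 2 and 5971 lower. Tomm22 (2.43), the splicing regulator Esrp1 (2.22), Anxa4 (2.06), the MHC class II chaperone Cd74 (1.73) and the helicase Ddx5 (1.70) were higher in series 2. Reg1 (-2.88), the mitochondrial gene ATP6 (-2.63), the chemokine Ccl25 (-2.57), the goblet cell peptide Tff3 (-2.44) and the Paneth cell defensin Defa23 (-2.43) were lower. Between the brightest and another kept probe of the same gene, among 1162 genes with means above 8, the series difference correlated at only r = 0.17, with 129 pairs called in opposite directions and 363 called in both. For the genotype effect the same pairs correlated at r = 0.89, with 1 pair called in opposite directions. Quantile normalization within each series called 19465 probes, of which 1.5% were higher in series 2, and median scaling called 14910, of which 12.1% were, against 52.3% here. These scalings shifted the median of all probes by -0.24 and -0.14, so directions between series are relative to that shift. Paired probes of the same gene shared the direction of the series difference in only 58.4% of the 1162 genes. The series differences named here therefore belong to single probes and may not hold for the gene.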

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

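The test of the difference of effect between series was planned, and the tests that weigh explanations for it and for the arrays with conflicting labels were chosen after the results had been seen. The effect of Prox1 deletion differed between series for 148 probes and for 17 of 113 named genes. The effect in series 2 minus that in series 1 was -4.889 log2 for Sema7a, -2.675 for Psca, -2.617 for Tomm22, -2.658 for Xpnpep2, -1.971 for Cyp11a1, -1.361 for Cd74, -1.316 for Msln, -1.027 for Scn2b, -0.71 for Gja1 and -0.536 for Anxa1. It was 4.116 for Reg1, 3.175 for Xist, 2.864 for Prelp, 2.37 for Cptp, 2.329 for Sis, 1.072 for Pdpn and 0.931 for Plekhs1. Several genes had crossed levels, with Sema7a high in Apc-Prox1-deleted series 1 and Apc-deleted series 2 organoids, and Prelp and Cptp high in the opposite pair of groups.

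Xist was high in the Apc-deleted organoids of series 1, and 1 of 8 Y-linked probes, of Eif2s3y, was high (8.27 log2) in the Apc-Prox1-deleted organoids of that series while the other 7 lay between 6.61 and 7.00, so animals of different sex were weighed as a source of these differences. Of the probes with a chromosome whose effect differed, 5.1% lay on X or Y, against 3% of those tested. Most of these probes thus did not lie on X or Y. Such a count cannot weigh effects of sex on other chromosomes, which stay open here and for the other series 1 calls. Different animals or strain background behind each group may contribute: 21 of 82 genes had another such gene within 10 tested genes on the chromosome, against a median of 9 and a highest of 27 in 10000 random draws (permutation p = 0.004, one-sided), and 13 for as many genes with the smallest p over both series. This test replaced a count of probes on in 1 group alone, 11 in all, that had decided nothing, and gene families that lie together, such as Reg1 and Reg3a, add to it. Origin of the cultures and any biological difference between series were not tested otherwise and stay open.

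Of the 2 arrays deposited under conflicting labels, the one labelled with both genotypes lay at 0.462 on an axis from the Apc-deleted (0) to the Apc-Prox1-deleted (1) libraries of series 2. With a spread of 0.189 between libraries this position excluded neither genotype, and on 4 probes it lay between the genotypes of series 2: the brighter Prox1 probe was at 9.55 (8.65 to 9.53 in Apc-Prox1-deleted and 10.05 to 10.91 in Apc-deleted libraries), next to the former, the dimmer one at 7.88 (7.04 to 7.15 and 8.24 to 9.02), Vim at 9.11 (7.18 to 7.64 and 10.86 to 12.07) and Notum at 10.1 (7.96 to 8.42 and 11.05 to 11.25). In series 1 these levels were within the range of the Apc-deleted libraries (9.42 to 10.44, 7.74 to 8.90, 8.76 to 11.29 and 9.62 to 11.31), and its genotype stays open. Its Defa31 level of 6.62, at the floor, argues against RNA from an Apc-Prox1-deleted series 2 culture mixed into an Apc-deleted sample. On an axis from series 1 (0) to series 2 (1) this array lay at 0.966 and the array labelled with both series at 0.978, with a spread of 0.049, so a wrong series 1 label is a candidate explanation for both, and no biological explanation was tested.

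On the array labelled Apc-Prox1-deleted in both series, which entered no comparison, Defa31 stood at 14.61 log2.

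In 6 of 114 probes of named genes, 1 of the 4 Apc-deleted series 1 libraries stood apart from the others by Dixon's test, where chance gives about 5.7, or 1 in 20. Replicate 2 stood apart for Capg (7.38 log2), Espn (9.91) and Car9 (9.81), and replicate 4 for Crip2 (8.76), Tomm22 (7.12) and Cd79b (7.01).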

How the results depend on the processing

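The tests with other sets of libraries for the arrays with conflicting labels, with the deposited ratios and without X and Y genes were chosen after seeing the data, as were the splits of the libraries. The others were planned. The choice of 10 libraries itself followed the results. With all 14 entries, as planned, 2535 probes were called over both series, 2201 in series 1, 186 in series 2, 53 for the difference of effects, 6789 between series, and 11 lists, with Prox1 at -1.08. That run enters 1 array under both genotypes and another under both series. Of 96 named genes called over both series, 37 lost the call with no series term, 20 with all 14 entries, 12 with the replicate block, and 9 each with a robust prior and with no variance trend. Of 93 tested with only series 2 libraries, 37 lost it. None changed direction in the alternatives in which it was tested, and Xist, which stood at 0.02 in series 2, was removed by the filter with only series 2 libraries. The deposited ratios, tested as they are, called 3231 probes, 2774 of them among the 3362, with Prox1 at -0.171 on the ratio scale, and 13 named genes lost the call. The adjusted p there was 0.822 for Psca, 0.958 for Tomm22, 0.805 for Id3, 0.68 for Chac1, 0.542 for Trib3, 0.211 for Xist, 0.165 for Ccn2, 0.143 for Ddit3, 0.0899 for Cd74 and 0.0526 to 0.0642 for Kctd12, Cyp3a13, Ect2 and Hes1. The variance trend of that run was fitted to mean ratios in place of expression levels. It therefore cannot tell a failed call from an effect of that trend. With X and Y genes left out, 0 of 93 lost the call. The remaining genes were fitted to the same libraries, so that run cannot weigh effects of sex on them. Another source of the values, no background correction, an offset of 50 and the BeadChip as a block had been planned and were not run, because the table of signals could not be matched to the samples. Probes near the floor of about 6.7 limit all counts, and the causes of the changes below were not tested.

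Over both series, where 3362 probes were called, the count was 918 with no series term, 5098 with array weights, 725 with only series 2 libraries, 922 at 1.5-fold or more, 1666 with the array of both genotypes as Apc-Prox1-deleted series 1, and 1921 to 3849 without 1 library. In series 1 (2192) it was 4611 with array weights, 1001 with that array so counted, 1177 at 1.5-fold or more and 740 to 2615 without 1 library. In series 2 (1086) it was 394 with median scaling, 377 with cyclic loess, 394 with quantile normalization within each series, 665 at 1.5-fold or more and 413 to 1258 without 1 library. There the array of both series gave 352 when counted in series 1 and 1632 in series 2, the array of both genotypes in series 1 gave 185, and both arrays under their series 1 labels gave 36.

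The difference of effects (148) was called for 64 probes with the filter met on all arrays, 73 with no variance trend and 66 to 166 without 1 library. It was called for 29 with the array of both series in series 1, 52 with the array of both genotypes as Apc-Prox1-deleted series 1, 19 with both arrays under their series 1 labels and 234 under their series 2 labels. Between series (12506) the counts were 19465 with quantile normalization within each series, 7352 with the filter met on all arrays, 7430, 7307 and 3572 with the same changes of series 1 labels, 2340 at 1.5-fold or more and 9975 to 12556 without 1 library. Of the 12 lists, 0 were called with an estimated correlation, 14 by fry, and 10 to 13 without 1 library. The goblet cell list turned to higher with only series 2 libraries (adjusted p = 0.224), while its p ranged to 0.507 over the alternatives. Prox1 ranged from -1.775 to -1.453 without 1 library.

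The deviations of same-numbered libraries from their group means correlated at -0.026 and 0.191 in series 1 and at 0.091 in series 2. In a group of 2 libraries the deviations mirror each other, so the series 2 value is the same for both pairs and the check says little. The numbers were not taken to pair the samples, because the labels tie them to nothing shared. With the replicate number as a block, 1996 probes were called over both series, 229 for the difference of effects, 1615 in series 1, 1217 in series 2 and 10 lists, without the Paneth (adjusted p = 0.0666) and goblet cell lists (0.0717), with Prox1 at -1.393. Of the 90 splits of the 10 libraries within series, 1, the real one, called as many as 3362 probes, the highest other calling 266. That excludes a chance labelling of these libraries. It cannot exclude a chance difference between the animals or cultures behind each group, since replicates may be technical. For lists, 5 of 90 splits called at least 12, the highest other 17 and the median of the others 5, so chance cannot be excluded. Between series 1 of 90 splits, the real one, called 12506, and the highest other 811, which excludes a chance labelling with the same limit.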

Other observations

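The genes named in this part and the test near Prox1 were chosen after their values were seen. Among the enteroendocrine genes, Neurog3, which starts the enteroendocrine fate, fell by 1.67 on the log2 scale (SE 0.25), and the hormone genes Sct (-1.34, SE 0.20) and Gcg (-1.24, SE 0.19) fell with Ghrl. Of the p53 targets, Phlda3 (1.16, SE 0.18), Zmat3 (1.14, SE 0.20) and Gtse1 (1.12, SE 0.13) rose, and of the NRF2 targets Cbr3 (1.24, SE 0.20) and Gclm (1.01, SE 0.18). The Wnt targets Apcdd1 (-1.40, SE 0.23), Dkk3 (-1.47, SE 0.25) and Sp5 (-0.91, SE 0.16) fell along with Axin2 (-0.41, SE 0.12), whose call was lost without any 1 of 5 libraries: Apc-Prox1-deleted series 1 replicate 1 (adjusted p = 0.137) or 2 (0.0715), Apc-deleted series 1 replicate 3 (0.0511) or 4 (0.0562), and Apc-deleted series 2 replicate 1 (0.0692). With all 14 entries the calls of Zmat3 (adjusted p = 0.102), Apcdd1 (0.16) and Axin2 (0.0893) were lost, and with the series 2 libraries alone those of Neurog3 (0.0547), Sct (0.0715), Phlda3 (0.0653), Zmat3 (0.144), Gclm (0.0509), Sp5 (0.319) and Axin2 (0.306). The Apcdd1 call was also lost with the deposited ratios (0.884), where the variance trend was fitted to mean ratios and may account for the loss.

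Some probes were on in 1 group and at the floor in the libraries of the other 3. Of 11 such probes, 9 were on in Apc-Prox1-deleted series 2 organoids, among them both probes of the Paneth cell defensin Defa31, at 14.59 and 14.55 log2, and the defensin-related AY761185 at 10.65. The remaining 2 were Xist probes in Apc-deleted series 1 organoids. The filter removed both Defa31 probes from the comparisons because they were on in 2 libraries.

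Alleles carried along with the floxed Prox1 allele could change genes near it, which was tested on the 100 tested genes nearest to Prox1, a window shifted because Prox1 lies near the end of its chromosome. Of these neighbours 14% were called over both series, against a median of 16% in equally long stretches and 15.9% of all genes, and 72.2% of stretches had at least as high a share. The share showed no excess of calls near Prox1, but it lay inside the spread of the stretches, so such alleles stay open for single genes.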
